A study of Arabidopsis thaliana with 3 samples.

How the data were processed

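Whole Arabidopsis thaliana Col-0 plants grown on plates were flooded with water or with 1 mM 2,4-D for 1 hour, and total RNA was labelled with biotin and hybridised to Affymetrix ATH1 arrays, per the labels. There were 3 arrays, 1 for water and 2 for 2,4-D. The labels do not say whether the treated samples came from separate plants or plates. The p-values rest only on the spread between the 2 treated arrays, taken over probe sets of like signal, and this spread may be technical. The deposited values are intensities on a linear scale, made by the authors with MAS5 per the submitters' processing notes. MAS5 combines the perfect-match and mismatch probes of a probe set into 1 signal and scales each array. The version and the scaling target are not given in the sources used here. On every array the mean of the middle 96% of the probe sets was 100, as scaling to a common trimmed mean would leave it. Detection calls were not used here. The table held 22810 probe sets, of which 64 were control probe sets, and the 22746 others were analysed.

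Probe sets were named through a table that pairs the array's probe sets with genes and the RefSeq gene table of assembly TAIR10.1, used for names only. The build behind the files is not given in the sources used here, so no coordinates are reported. Of the 22746 probe sets, 13513 had 1 gene symbol, 503 had several and 8730 were not listed in the naming table. A locus in the RefSeq table was found for 13436. A probe set with several genes was not named, and a probe set without a name here is not one without a gene. Many well-studied genes fell among the unlisted probe sets: of 382 genes in the fixed lists, 61 had a named probe set and 42 were tested. Of the 24 largest rises and the 24 largest falls among all tested probe sets, 17 and 16 had no single name.

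The signals were taken to log2 without further normalization or an offset. Probe sets were tested when their mean signal over the 3 arrays was at or above the 40th percentile, which was 24.8, and 13648 passed. This mean holds 2 treated arrays and 1 water array, so dim genes that rose with 2,4-D passed more easily than those that fell. PDC2 (5.39 with water, 37.9 and 39.3 with 2,4-D) was tested, and EXPA18 (43.8 with water, 7.98 and 3.55 with 2,4-D) was not. The groups were compared with lmFit and eBayes with an intensity trend in limma 3.58.1 under R 4.3.3, with Benjamini-Hochberg adjustment over the tested probe sets and a threshold of 0.05. The fit had 1 residual degree of freedom, from the treated arrays, and the lone water array was assumed to vary as they do. The estimated prior degrees of freedom were infinite, which means that the variance of each probe set was read entirely from the trend over signal and its own spread between the treated arrays had no weight. Standard errors are those of this fit. The number of arrays limits the precision. A second count used size alone: a change of at least 2-fold in the same direction on both treated arrays. Its chance level was simulated 100 times with 1 shared water array and residuals drawn within signal bins from the treated pair.

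Lists of 382 genes in 19 groups were tested with camera in limma at a preset correlation of 0.01 where at least 3 members were tested, which held for 6 lists. A member carried by several probe sets was represented by the one with the highest mean signal. Medians of lists were also placed among 10000 random lists of the same size matched on signal. The genes named are the 12 with the largest rise and the 12 with the largest fall among called probe sets with 1 gene and at least 2-fold changed on both treated arrays, and from each list up to 4 members with the largest change and every member past adjusted p. The ranks used fitted changes without a floor on dim signals. These lists, this rule, the tests and all alternatives other than those said to be chosen later were fixed before the data were examined. Low signals were judged against 27 probe sets for bacterial transcripts that were dim on all 3 arrays. The brightest of them was 13.9 on the water array, 10.7 on 2,4-D replicate 1 and 8.38 on 2,4-D replicate 2, and 26.5%, 26.3% and 22.9% of the probe sets lay at or below it. A gene at or below it in 1 group has its change given as a lower bound against that value, by a rule chosen after seeing the data.

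The tests were tried on simulated data for the comparison of 2,4-D with water, over 13648 probe sets of which 200 were changed. The fit recovered 80.3% of changes of 2 log2 units, 31.3% of changes of 1 unit and 1.49% of changes of 0.5 units, with 0 false calls among 13448 unchanged probe sets. All 3 simulated arrays had the treated pair's spread at each signal, as the fit assumes. False calls from a variance particular to a gene or from a deviating water array could therefore not appear. With 200 changed probe sets simulated against 2906 calls in the data, these rates need not carry over. In a run of camera on 51 simulated sets, the shifted set was found and 0 of the others had p under 0.05.

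The alternatives were quantile normalization, scaling each array to 1 median, an offset of 7.44 (the 20th percentile of all signals) before log2, no filter, a filter at the 60th percentile, leaving out probe sets whose identifiers mark possible cross-hybridisation, limma without the trend or with a robust prior, fold thresholds of 1.5 and 3, camera with an estimated correlation, fry, and leaving out each treated array. A floor at the brightest dim control, and groups of genes formed from symbol stems or plastid location, were added after seeing the data. The control probe sets were left out of all tests.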

Results

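Expression was measured in young whole plants of Arabidopsis thaliana Col-0, the standard laboratory accession, after flooding with either water or the synthetic auxin 2,4-dichlorophenoxyacetic acid (2,4-D). This compound acts through the auxin receptors and is used as a herbicide against broad-leaved plants. Plants were treated for 1 hour, the herbicide was applied at 1 mM, and each RNA sample was hybridised to 1 Affymetrix ATH1 array. The water group held 1 array and the 2,4-D group held 2 arrays. The median MAS5 signal was 41.9 on the water array, 38.7 on 2,4-D replicate 1 and 38.5 on 2,4-D replicate 2. The log2 signals of the treated arrays correlated with r = 0.974 across the tested probe sets, against 0.910 and 0.906 between the water array and each treated array. Probe sets are not independent replicates, so these coefficients describe the arrays only. Control transcripts from bacteria and phage also differed between arrays. The geometric mean signal of the bioB control was 228 on the water array, 102 on 2,4-D replicate 1 and 79.8 on 2,4-D replicate 2, and that of bioC was 621, 303 and 215. The brighter bioD (1060, 871 and 735) and cre (4400, 3600 and 4120) controls lay closer together. The ratio of 3' to 5' signal for the GAPDH transcript was 1.22, 1.27 and 1.12 on the same arrays. For the ubiquitin transcript it was 1.64, 1.45 and 1.40, and for actin 3.46, 2.91 and 3.41.

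The comparison of 2,4-D with water asked which transcripts changed at a herbicidal level of the auxin. Within 1 hour the auxin-responsive genes GH3.3, HAT2 and IAA30 rose, as did the dehydration-responsive genes COR15A, COR47 and LEA4-5 and the ubiquitin ligase gene PUB19. Genes for proteins that loosen the cell wall went both ways, with XTH16 and EXPA8 lower and EXPA16 higher, and EXO, a gene tied to cell expansion, fell. Among the 13648 probe sets tested with limma, 1472 were higher and 1434 were lower with 2,4-D past the adjusted p threshold of 0.05.

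The largest rise among probe sets with a single named gene was that of PUB19 (AT1G60190), which encodes a U-box E3 ubiquitin ligase that acts in abscisic acid and drought responses. Its signal was 19.1 with water and 712 and 1070 with 2,4-D, a log2 change of 5.52 ± 0.20 (SE, n = 2 against 1) or 45.8-fold. AT1G20070 rose 12.3-fold (log2 change 3.63 ± 0.20), and AT1G48100, which encodes a polygalacturonase that cuts pectin, rose 11.3-fold (3.5 ± 0.20). COR15A (AT2G42540), whose product protects chloroplast membranes during freezing and drying, rose 8.84-fold (3.14 ± 0.22). AT2G41190 rose 7.97-fold (2.99 ± 0.23) and AT2G16005 rose 7.18-fold (2.84 ± 0.23). The other risers in this group had a water signal no brighter than the brightest of the dim bacterial controls, so that only a lower bound could be given for their change. Their place among the largest rises is therefore not resolved. With dim signals raised to the control's, the log2 change was 1.68 for ndhG, 1.38 for AT3G25610, 1.92 for LEA4-5 and 1.86 for ROXY1. These lay below GH3.3 (2.33) and HAT2 (2.29), which are not in this group. AT3G56260 was at least 8.7-fold higher, with signals of 5.45 for water and 111 and 131 for 2,4-D. AT5G16960 was at least 5.88-fold higher, LEA4-5 (AT5G06760, a late embryogenesis abundant protein made in drying tissue) at least 3.78-fold and the glutaredoxin gene ROXY1 (AT3G02000) at least 3.64-fold. The plastid gene ndhG, for a subunit of the chloroplast NADH dehydrogenase-like complex, was at least 3.21-fold higher, and AT3G25610, for a phospholipid-transporting ATPase, at least 2.6-fold.

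Falls among the named genes that passed the filter were smaller than the highest rises. AT5G50335 fell by 3.38 ± 0.53 on the log2 scale, from a signal of 97.6 with water to 5.74 and 15.3 with 2,4-D, the first of which was below the brightest dim control of its array (log2 change -2.93 with that signal raised to the control's). AT5G57760 fell by 3.33 ± 0.41, from 149 to 19.6 and 11.2. EXO (AT4G08950), a gene induced by brassinosteroids that promotes cell expansion, was 4.99-fold lower, with a signal of 492 for water and 133 and 73.2 for 2,4-D. AT5G02540 was 4.98-fold lower (log2 change -2.32 ± 0.30) and AT3G19850 4.44-fold lower (-2.15 ± 0.29). The transcription factor gene BZIP61 (AT3G58120) was 4.17-fold lower (-2.06 ± 0.27), and AT2G25250, with signals of 307 for water and 74.2 and 71.5 for 2,4-D, was 4.21-fold lower. AT3G52550, AT4G16000 and AT1G26300 were 4.36-fold, 4.35-fold and 4.1-fold lower. AT3G61400 had signals of 48.9 for water and 18.0 and 7.68 for 2,4-D, the last below the brightest dim control of its array, and a log2 change of -1.99 with that signal raised to the control's. Of these 24 genes AT3G61400 had the highest limma adjusted p, 0.00244, and its call ended when all probe sets were tested without a filter (adjusted p = 0.0885).

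**Figure D1:**
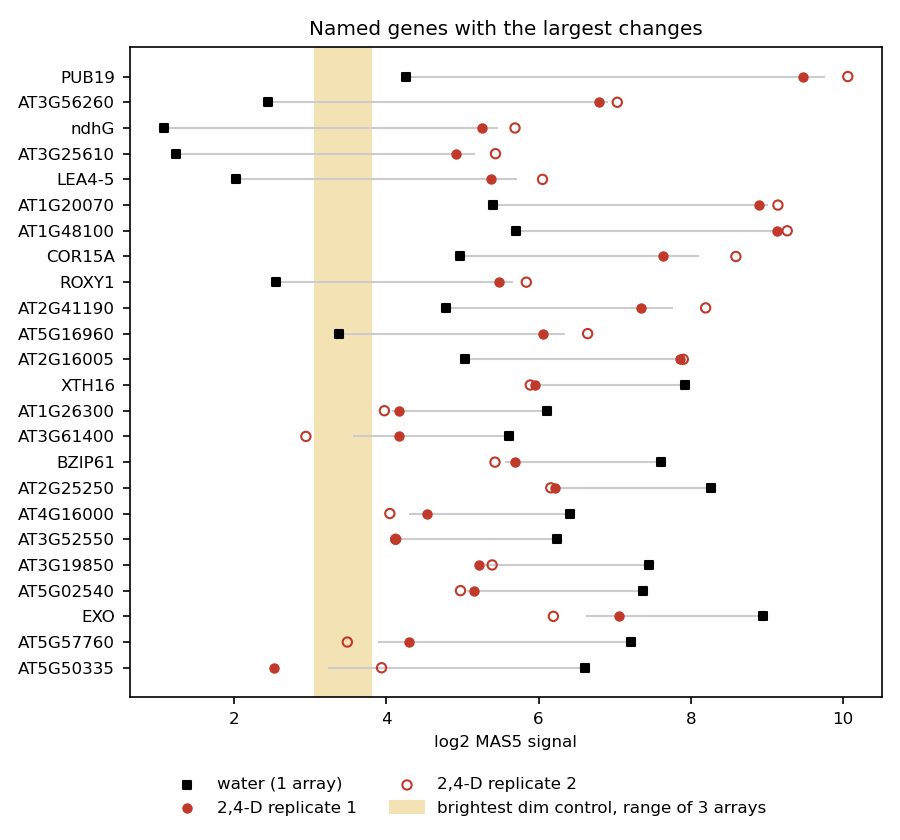
Log2 MAS5 signal (horizontal axis) of the 12 named genes with the largest rise and the 12 with the largest fall, ranked without a floor on dim signals, with 1 square for the water array, 1 filled and 1 open circle for the 2,4-D arrays, and a line from the water value to the 2,4-D mean. The shaded band spans the brightest dim bacterial control on each array (linear signal 8.38 to 13.9), and the water signals of AT3G56260, ndhG, AT3G25610, LEA4-5, ROXY1 and AT5G16960 lie at or left of their array's value.

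The auxin lists drawn up for the comparison covered the Aux/IAA repressors, the GH3 enzymes that join auxin to amino acids, the SAUR genes and other genes of auxin response and transport. Of the 8 members that could be named and tested, 3 rose and 0 fell. The filter let in dim genes that rose more easily than dim genes that fell. Among named members too dim to be tested, PUCHI (26 for water, 17.3 and 13.7 for 2,4-D) and IAA33 (17.2, 5.08 and 10.3) had lower signals. GH3.1, GH3.9, LBD29 and IAA34 had higher signals on both treated arrays, and IAA20 and IAA31 went both ways. GH3.3 (AT2G23170) rose 5.03-fold, with signals of 109 for water and 509 and 595 for 2,4-D (log2 change 2.33 ± 0.19). HAT2 (AT5G47370), an auxin-induced homeodomain-leucine zipper gene, rose 4.89-fold, with 293 for water and 1430 and 1440 for 2,4-D (2.29 ± 0.21). IAA30 (AT3G62100), an Aux/IAA protein without the usual degradation motif, rose by 1.97 ± 0.39 on the log2 scale from a water signal of 13.9 that lay just above the brightest dim control, to 53.3 and 55.7. The other tested members did not pass: the log2 change was 0.04 ± 0.21 for IAA18, -0.33 ± 0.24 for IAA29, 0.28 ± 0.20 for GH3.5, -0.20 ± 0.22 for GH3.17 and -0.09 ± 0.42 for LBD16. The GH3 list as a whole passed the camera set test (adjusted p = 0.0174 over the 6 lists with at least 3 tested members, median log2 change 0.28 over 3 genes), with GH3.3 as the only member that passed. The call was lost after quantile normalization (adjusted p = 0.115) and with a stricter filter (adjusted p = 0.0752). It was also not made by camera with an estimated correlation (adjusted p = 0.747). That form of camera rests here on the 1 residual degree of freedom, and its lowest unadjusted p for any list was 0.204. Its loss therefore says little about the list. The Aux/IAA list did not pass (adjusted p = 0.54, median 0.04). Counts adjusted over the list alone were the same as over all genes, with 1 of 3 Aux/IAA, 1 of 3 GH3 and 1 of 2 other auxin genes higher.

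Both tested members of the abscisic acid list rose. COR15A is given above, and the dehydrin gene COR47 (AT1G20440) rose 2.52-fold, with signals of 747 for water and 1590 and 2220 for 2,4-D (log2 change 1.33 ± 0.23). PDC2 (AT5G54960), a pyruvate decarboxylase gene of ethanol fermentation and the single tested gene of the low oxygen list, was at least 2.78-fold higher, with 5.39 for water against 37.9 and 39.3. In the list of touch, wound and rapid stress genes 1 of 4 rose, the senescence-related transcription factor gene WRKY53 (AT4G23810) with a log2 change of 1.80 ± 0.37, and 2 of 4 were higher when adjusted over the list alone. The change was 0.78 ± 0.31 for WRKY6, -0.38 ± 0.34 for WRKY22 and -0.18 ± 0.20 for ZAT10, and the list did not pass (adjusted p = 0.54, median 0.30). Of the 8 tested xenobiotic detoxification genes 1 rose and 1 fell. The glucosyltransferase gene UGT73B5 (AT2G15480) rose by 1.81 ± 0.41, to 43.1 and 56.5. Its water signal of 14.1 lay just above the brightest dim control. The glutathione transferase gene GSTU27 (AT3G43800) fell by 0.94 ± 0.22. GSTU26 (0.58 ± 0.34) and GSTU25 (-0.12 ± 0.29) did not pass. The median of that list was -0.0010 and its mean 0.17, camera's direction was upward, and it did not pass (adjusted p = 0.856). The sign of its median turned with both other scalings of the arrays and without a filter. In ethylene signalling EIN3 (AT3G20770), the main transcription factor of the pathway, was 1.69-fold lower (log2 change -0.75 ± 0.19, adjusted p = 0.00121), a call lost without the intensity trend (adjusted p = 0.0735). RTE1, which promotes the activity of the ETR1 receptor, had a change of 0.70 ± 0.29 (adjusted p = 0.0638). It was called higher when adjusted over the list alone, where the 2 tested ethylene genes gave 1 higher and 1 lower. Both other scalings of the arrays also called RTE1 higher over all genes. Adjustment over the list alone left the abscisic acid, low oxygen and xenobiotic counts as they were.

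Of the 9 tested genes of the fixed list of expansins and xyloglucan endotransglucosylase/hydrolases, which loosen the cell wall, 3 fell and 1 rose, and the counts were equal when adjusted over the list alone. XTH16 (AT3G23730) was 3.99-fold lower, with signals of 242 for water and 62.0 and 59.3 for 2,4-D. EXPA8 (AT2G40610) was 3.31-fold lower, with 969 for water and 307 and 279 for 2,4-D (log2 change -1.73 ± 0.19). XTH18 (AT4G30280) was 1.99-fold lower, with signals of 67.2 for water and 28.8 and 39.4 for 2,4-D (adjusted p = 0.0274), a call that ended after scaling the arrays to 1 median (adjusted p = 0.0567) and without a filter (adjusted p = 0.123). EXPA16 (AT3G55500) rose by 1.70 ± 0.34. Over all 13 named expansin and XTH genes tested, a count chosen after the values were seen, 3 were lower and 3 higher. EXPA15 (log2 change 0.99 ± 0.20) and XTH32 (1.01 ± 0.19), which lay outside the list, rose too. The filter let in dim genes that rose more easily than dim genes that fell. XTH33, the list's other named member, was too dim to be tested, with 41.2 for water and 10.7 and 13 for 2,4-D. The untested expansin genes EXPA7 and EXPA18, outside this list, also had lower signals with 2,4-D. The list's median of -0.38 lay at percentile 4.89 of 10000 random lists matched on signal, and the list did not pass camera (adjusted p = 0.0589, and adjusted p = 0.747 with an estimated correlation). The estimated correlation left camera 1 residual degree of freedom, so the latter value says little.

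**Figure D2:**
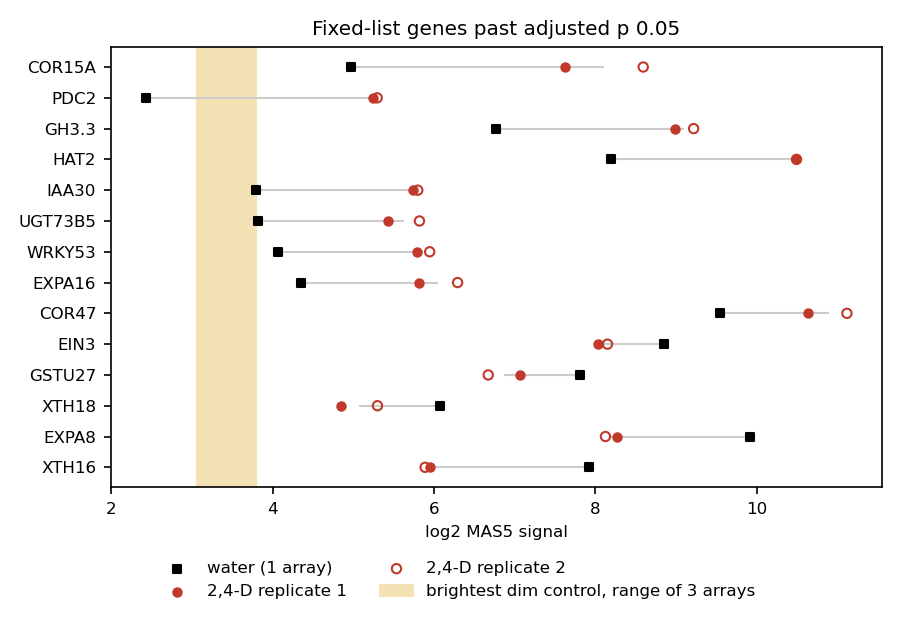
Log2 MAS5 signal (horizontal axis) of the 14 genes from the fixed lists that passed adjusted p 0.05, with 1 square for the water array, 1 filled and 1 open circle for the 2,4-D arrays, and a line from the water value to the 2,4-D mean. HAT2 (linear signal 293 to 1430 and 1440) and EXPA8 (969 to 307 and 279) moved in opposite directions, and the shaded band spans the brightest dim control on each array.

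Among the tested genes that report on tissue makeup and general state, 0 were called over all genes tested. The nuclear photosynthesis genes had log2 changes of -0.49 ± 0.34 for LHCB4.2, -0.25 ± 0.39 for LHCB4.1 and -0.17 ± 0.40 for RCA, and 0 of 3 passed, also when adjusted over the list alone (camera adjusted p = 0.664, median -0.25). The root-expressed beta-glucosidase gene BGLU23 (PYK10), the single tested root marker, changed from 2240 for water to 2980 and 2440, within 1 SE of no difference (0.27 ± 0.28), and did not pass over the list alone. The root-hair expansin genes EXPA18 and EXPA7, root markers too dim on average to be tested, had lower signals with 2,4-D, 43.8 for water against 7.98 and 3.55 for EXPA18 and 37.0 against 15.1 and 15.3 for EXPA7. The clock gene GI had a change of 0.78 ± 0.32 (adjusted p = 0.0659) and was called higher when adjusted over the list alone, where it was the only member. The cytokinin response regulator ARR15 (0.44 ± 0.37) and the reference genes UBC21 (0.32 ± 0.20) and TIP41L (-0.54 ± 0.25) did not pass by either adjustment. The lists for SAUR genes, ethylene biosynthesis, jasmonate, heat shock, and gibberellin and brassinosteroid metabolism had 0 members both named and tested.

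By size alone, 519 probe sets were at least 2-fold higher and 429 at least 2-fold lower on both treated arrays than on the water array. Simulated arrays without an effect, which kept the shared water array and the spread between the treated arrays, gave a mean of 24.2 higher and 24.3 lower, with at most 35 and 36 in 100 simulations. They hold no variation of the water array beyond the spread of the treated pair, so any other peculiarity of that array would also raise the observed counts. The counts were 654 higher and 266 lower after scaling the arrays to 1 median, 386 and 283 with an offset before log2, and 351 and 212 with a stricter filter, and without a filter 1339 probe sets were higher and 1964 lower. With 2,4-D replicate 1 left out, 716 were at least 2-fold higher and 768 lower on the remaining treated array, and with 2,4-D replicate 2 left out, 719 and 706. Of the 513 called probe sets that were also at least 2-fold higher on both arrays, 238 carried 1 named gene, and of the 418 called and at least 2-fold lower, 206 did. Unlisted probe sets also changed strongly. The pair with the highest fitted rise had signals of 2.21 for water and 132 and 236 for 2,4-D (at least 12.7-fold higher), and of 0.948 for water and 69.4 and 88.1 for 2,4-D (at least 5.64-fold higher). Of the pair with the lowest fitted change, 1 had signals of 124 for water and 12.4 and 18.1 for 2,4-D (log2 change -3.04 ± 0.42). The other had 112 for water and 1.34 and 21.3 for 2,4-D, of which 1.34 was below the brightest dim control, and a log2 change of -2.89 with that signal raised to the control's.

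**Figure D3:**
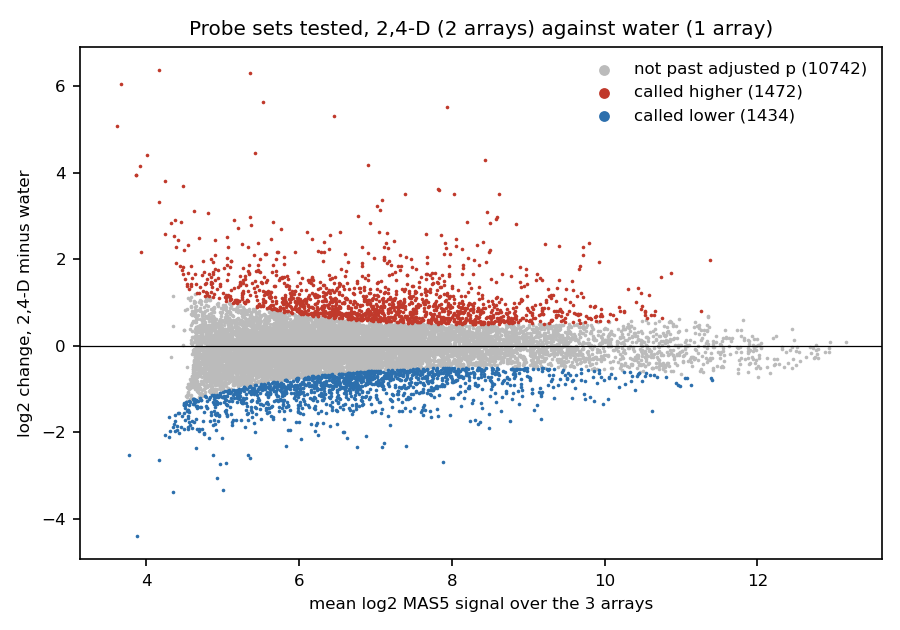
Log2 change of 2,4-D minus water (vertical axis) against the mean log2 MAS5 signal over the 3 arrays (horizontal axis), with 1 point for each of the 13648 probe sets tested. The 1472 probe sets called higher are red, the 1434 called lower are blue, and the change needed for a call is larger at low signal.

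The calls had no second water array behind them, since the single residual degree of freedom came from the treated pair and the variance was taken wholly from its trend over signal. Without that trend 834 probe sets were higher and 839 lower, and without the filter on low signal 964 were higher and 710 lower. Scaling the arrays to 1 median moved the median change of all tested probe sets from -0.04 to 0.07 and the split to 2031 higher and 991 lower, so that 67.2% of the calls were higher against 50.7%.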

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

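The search behind these values was chosen after the data were seen. Genes of the fixed lists that were too dim on average to be tested were searched for a signal above the brightest dim bacterial control in 1 group only and differing at least 2-fold between the water array and each treated array. EXPA18, a root-hair expansin gene, was found on the water array only, with a signal of 43.8 against 7.98 and 3.55 with 2,4-D, at least 4.62-fold lower. The other genes, 3 in number, were above that level on the treated arrays only. GH3.1, an auxin-conjugating enzyme gene, had a signal of 3.21 with water and 12.7 and 16.3 with 2,4-D, a geometric mean of 14.4 for 2,4-D and at least 1.04-fold higher. LBD29, an auxin-induced gene of lateral root formation, had 5.71 with water and 14.1 and 12.5 with 2,4-D, a geometric mean of 13.3. JMT, which encodes the enzyme that methylates jasmonic acid, had 2.01 with water and 12.5 and 12.7 with 2,4-D, a geometric mean of 12.6. The means of LBD29 and JMT were under the brightest dim control of the water array (13.9), so no fold is given for them, and none of these differences was tested. Among all 9098 untested probe sets, 299 were above that level on both treated arrays and not on the water array, and 449 were above it on the water array and on neither treated array, in each case with at least a 2-fold difference. The filter used the mean of 2 treated arrays and 1 water array, so signal on the water array only was more easily left untested.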

How the results depend on the processing

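The floor on low signals was the only alternative here chosen after seeing the data; it gave 1476 higher and 1440 lower and changed no call of a named gene. Calls higher and lower were 1589 and 1396 after quantile normalization, which kept 92.7% of the calls with their direction, and 2031 and 991 after median scaling, which kept 84.9%. Without a filter there were 964 and 710, over 22746 probe sets, and without the intensity trend 834 and 839; the infinite prior degrees of freedom fell to 8.38 there, and 53.3% of the calls were kept. The probe sets at least 2-fold lower on both arrays numbered 266 after median scaling, 283 with the offset and 212 with the stricter filter, which tests fewer probe sets. Without a filter 1339 were higher and 1964 lower, at 1.5-fold 1316 and 1428, and at 3-fold 169 and 60. The GH3 median was 0.21 after quantile normalization (adjusted p = 0.115), 0.28 with the stricter filter (0.0752) and 0.28 with an estimated correlation (0.747), and its adjusted p in fry was 0.0129. The estimated correlation left camera 1 residual degree of freedom, so a list could hardly pass it. The cell wall list passed with the stricter filter, which left 5 members (median -0.38, adjusted p = 0.0192). The xenobiotic median turned to 0.036 after quantile normalization, 0.12 after median scaling and 0.078 without a filter, and the change of LBD16 turned to 0.077 after quantile normalization and 0.030 after median scaling. Apart from the smaller or larger number of probe sets tested and the prior degrees of freedom, the cause was not tested. The latter were 52.3 with quantile normalization, 35.4 with the stricter filter and 11.2 without a filter, against infinite in the main fit. XTH18 (-0.996) and AT3G61400 (-2.05) had the same log2 changes without a filter as in the main fit. With 1 treated array left out there was no residual degree of freedom and no test. The count at least 2-fold higher was then 716 to 719 and lower 706 to 768, and list medians ranged from -0.17 to 0.27 for Aux/IAA, 0.27 to 0.30 for GH3, -0.019 to 0.12 for xenobiotic, 0.13 to 0.54 for touch, -0.59 to 0.082 for photosynthesis and -0.37 to -0.29 for cell wall genes. Of the 55 named genes, 3 were gained by quantile normalization and the same 3 by median scaling (RTE1, WRKY6 and GI), and calls were lost for XTH18 (median scaling, no filter), AT3G61400 (no filter) and EIN3 (no trend). The stricter filter left 31 of the 55 to be tested, without IAA30, WRKY53, UGT73B5, PDC2, EXPA16, LEA4-5 and ndhG among others, and AT3G61400 was not tested after median scaling. Leaving out probe sets open to cross-hybridisation changed none of these. The robust prior varied nothing, since its prior degrees of freedom were infinite as in the main fit and its values were the same. No paired analysis was possible because the groups share only 1 replicate number. Signal over background limits the dim genes: 26.5% of probe sets on the water array were no brighter than its brightest dim control.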

Other observations

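The gene groups in this part and the tests of them were formed after it was seen which probe sets could be named; of the tests weighed below, the choice of the lone array, the single water array and the share of green tissue were chosen after the results were seen. Of 64 plastid-encoded genes tested, 20 rose, 8 fell and the others did not pass, and 43 had a change above 0, with a median log2 change of 0.43 (0.29 on 2,4-D replicate 1 and 0.51 on 2,4-D replicate 2). The group passed camera in limma (adjusted p = 0.0165 over 29 groups), a call that was lost with an estimated correlation (adjusted p = 0.913) and with the stricter filter (adjusted p = 0.0555 over 26 groups) and was not made by fry (adjusted p = 0.482). Camera with an estimated correlation rested on 1 residual degree of freedom. Its lowest unadjusted p over the 29 groups was 0.222, so the loss there says little. psbB, for a core antenna protein of photosystem II, rose by 1.92 ± 0.23 on the log2 scale, the intron maturase gene matK by 1.3 ± 0.21, accD, for a subunit of the plastid acetyl-CoA carboxylase, by 1.24 ± 0.33 and the ATP synthase gene atpA by 1.01 ± 0.21. The changes were -1.51 ± 0.24 for psaJ and -1.63 ± 0.36 for psbT, which encode small photosystem subunits, and 0.78 ± 0.20 for psbH, which encodes another. The counts were 24 higher and 7 lower after quantile normalization and 26 higher and 3 lower after median scaling.

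Among families formed by gene symbol, the tetraspanins, membrane proteins that organise other proteins in the plasma membrane, had 4 of 7 tested members higher and 0 lower under all 3 scalings of the arrays. TET8 rose by 1.33 ± 0.20, from a signal of 360 with water to 947 and 861, TET2 by 1.53 ± 0.33, TET7 by 0.75 ± 0.20 and TET3 by 0.63 ± 0.22, and the family did not pass camera (adjusted p = 0.197). Of 22 tested UDP-glycosyltransferase genes, 5 rose and 0 fell (6 and 0 after median scaling), with camera adjusted p = 0.454. Among the risers were UGT73B1 (1.23 ± 0.30), UGT78D2 (1.13 ± 0.21) and UGT74B1 (0.70 ± 0.20, an enzyme of glucosinolate synthesis). The median log2 change of this family was 0.253 on 2,4-D replicate 1 and 0.0249 on 2,4-D replicate 2. Of 9 tested IQD genes, whose products bind calmodulin and microtubules, 3 fell and 1 rose under each scaling, with -1.52 ± 0.36 for IQD19, -1.07 ± 0.23 for iqd32, -0.65 ± 0.20 for IQD31 and 1.04 ± 0.29 for IQD23 (adjusted p = 0.454). The ubiquitin ligase family PUB passed camera (adjusted p = 0.000336) with 1 of 6 members, PUB19, higher and 1 lower, a result that was lost with an estimated correlation (adjusted p = 0.913), after quantile normalization (adjusted p = 0.283) and without a filter (adjusted p = 0.289). The first of these losses says little, since camera with an estimated correlation had 1 residual degree of freedom. The families described here were among 29 groups. Over all 13648 probe sets tested, 1472 were higher and 1434 lower. Some small families may have calls mostly in 1 direction by chance, which was not tested.

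The first pattern weighed was the near-equal number of probe sets called higher (1472) and lower (1434). This balance moved with the centring of the arrays, from 50.7% higher at the deposited scale to 53.2% after quantile normalization and 67.2% (2031 against 991) after median scaling. It also moved with the filter, to 57.6% higher without one and 54.3% with the stricter one. The filter's mean signal held 2 treated arrays and 1 water array, which eased the entry of dim genes that rose. By size alone, 519 higher and 429 lower became 1339 and 1964 without a filter. After quantile normalization 92.7% of the calls kept their direction and their side of the threshold, which bears on the calls and not on their balance, so that a difference in scale between the arrays stays open for the balance. On the deposited scale the direction of change tilted with signal. The median log2 change was -0.214 in the dimmest decile of tested probe sets, 0.0793 in decile 9 and -0.0126 in the brightest. Calls in these deciles were 78 higher and 139 lower, 257 and 156, and 152 and 115. With the arrays regrouped so that each in turn was the lone one, the water array gave 2906 calls and the highest of the others gave 0, with 112 probe sets at an unadjusted p under 0.05. Only the real choice, 1 of 3, gave as many calls, but any other choice mixes water and 2,4-D in 1 group, which widens its spread, and 3 choices are too few for a share under 0.05. With 1 water array, a property of that array other than its treatment cannot be told apart from 2,4-D, and the 2.53-fold brighter bioB control on it is a difference from the treated arrays outside the plant transcripts; the response to 2,4-D stays open beside it.

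The second pattern was the positive median change of the plastid-encoded transcripts. A difference in scale that varies with signal was argued against as its whole cause, because their median log2 change was 0.46 after quantile normalization at percentile 100, rounded, of 10000 random sets matched on signal. The random sets held genes drawn independently, so this percentile does not allow for plastid transcripts that move together. The shift was not confined to bright or to dim members: the median was 0.50 in the dimmer 32 genes and 0.411 in the brighter 32. This split does not test a few members as the cause. A median with 43 of 64 changes above 0 cannot be set by a few of them. A larger share of green tissue in the treated samples could not be excluded, since only 1 of 3 nuclear photosynthesis genes (LHCB4.2) lay below 0.215, the midpoint between 0 and the plastid median, by over 2 SE, none of the 3 was called, and the dim root-hair genes EXPA18 and EXPA7 had lower signals with 2,4-D while the root marker BGLU23 did not. How plastid RNA, most of which lacks long poly(A) tails, was primed is not given in the sources used here, and differences in priming or in the single water array may also contribute and were not tested.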
